A study of Homo sapiens with 10 samples.

How the data were processed

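Total RNA was extracted with the miRNeasy kit, per the labels, from DLD1 cells and 3 derived lines grown in McCoy's medium, and hybridised in 1 colour (Cy3) to Agilent human miRNA arrays. Each of the 10 deposited scanner files holds 1 array with spot intensity, and the spot intensities were extracted and background-subtracted with Agilent Feature Extraction 10.7.3.1, per the file headers. Negative values occur after that subtraction, and 3.07% of the spots carried an outlier flag. No spot was saturated. A further table of the authors holds 1 intensity per probe and array on a linear scale; its columns have nearly equal medians, at 41.3, 41.3, 41.2, 41.2, 41.2, 41.2, 40.9, 41.2, 41.0 and 41.2 in the order DLD1, SA, SPH, METS, so the arrays appear normalized to each other by a method not given in the sources used here, and background was not subtracted. R 3.2.0 stands in the submitters' processing notes. Each column was set against the scanner files over the 379 probes well above background on all arrays. After subtraction of column medians and probe means, 10 of 10 columns correlated most with their own array (0.84 to 0.92, against 0.38 to 0.75 for the highest other array). On the log2 scale the slopes on the array's median spot signal were 0.97 to 1.05, so scale and direction are known and probes were not centred. The normalization stays unknown. It was used as an alternative only.

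Spots with an outlier flag and control spots were left out, and the background-subtracted signals of a probe's spots were averaged. Since under 10% of the probes were well above background, each array was divided by the 75th percentile over the 379 probes well above background on all 10 arrays. Values were then floored at 0.0791, the median over arrays of the 1st percentile among probes well above background, and taken to log2. A miRNA was represented by the brightest of its probes, and 239 miRNAs with a probe well above background on every array of at least 1 line were tested. Names are those of the array design, without the species prefix. 233 of the 239 matched a miRNA gene in a table of the GRCh38.p14 assembly, which was used for names and for which genes are neighbours; the array was designed on hg19, so no coordinates are given. Probes of related miRNAs (let-7 members, miR-192-5p and miR-215-5p, miR-17-5p with miR-20a-5p and miR-20b-5p) can cross-hybridise, and their values are not fully independent. miR-1246 also matches a fragment of a small nuclear RNA, which the array does not separate.

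A mean per line was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment within each of 6 comparisons and a threshold of 0.05 on the adjusted p. The 6 comparisons, the 26 miRNA lists, the alternatives and the rule for naming miRNAs were fixed before the data were examined. Where no array of the dimmer line was well above background, the difference is given as "at least", comparing the brighter line's mean with the higher, per array, of the lowest signal among probes well above background and the probe's own signal; these bounds can exceed the fitted fold, which the floor limits. Lists with at least 3 tested members were tested with camera (inter-gene correlation 0.01), adjusted over the lists within a comparison; camera with an estimated correlation made 0 of the 24 calls of the preset. The rule named, among called miRNAs with no overlap between the arrays compared and well above background on the higher side, the 10 highest and 10 lowest changes (6 and 6 for SPH versus SA and for METS versus SA and SPH). It also named up to 4 members of each described list by adjusted p, and the main strands of the miR-200 family. On simulated data for SA versus DLD1 (239 miRNAs, 60 of them changed), 90.8% of changes of 0.5 and 41.2% of changes of 0.25 on the log2 scale were recovered. The shares were 93.5% and 38.5% for METS versus DLD1, and 87.8% and 32.2% for SPH versus DLD1. The simulated noise was independent, without slide or brightness differences.

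Alternatives covered the percentile set, quantile normalization, no scaling, normexp background correction, the scanner's total signal per miRNA, the authors' table, probe summary, detection filter, floor, spots with an outlier flag kept, samples in the fit, moderation, array weights, replicate number, slide, array row and each array left out. Normexp was run on the median spot signal, because the mean spot signal planned for it is not among the columns used here. A check on viral miRNAs, also planned, was not run, since none was among the probes. Added after seeing the data were brightness as a covariate, the 2 brightest SPH and METS arrays left out, and slide 1 alone. No 2 arrays of a line differed by as little as the noise between spots, the closest being SA 2 and SA 3 (2.14 times the median squared difference that spot noise gives). The arrays were kept as separate replicates, as labelled. Repeat hybridisations of 1 RNA can also differ by more than spot noise, so whether the arrays come from separate cultures stays unknown. The precision is limited by the 2 or 3 arrays per line.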

Results

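The series measured microRNAs (miRNAs) on 10 single-colour arrays of the human colorectal cancer cell line DLD1 and of 3 lines derived from it. DLD1 itself, labelled epithelial, was measured on 2 arrays. The SA line, from colonies grown in soft agar, was measured on 3 arrays and the SPH line, from colonospheres (floating spheres of colon cancer cells), on 2 arrays; the labels give both as mesenchymal, and as mesenchymal-like in their titles. The METS line, from a lung metastasis of a xenograft and again labelled epithelial, was measured on 3 arrays. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Each line is a single derivation. The array carried 2549 human miRNAs on 5893 probes. Between 6.91% and 7.84% of the probes were well above background per array, which gave 224 to 249 detected miRNAs, and 239 miRNAs were tested. The spots of miR-7975 and miR-7977 together took 48.5% to 57.4% of the summed probe signal. The 75th percentile of the signal, here called brightness, was 303 ± 21.2 (SD, n = 2) in DLD1, 358 ± 35.8 (n = 3) in SA, 414 ± 78.6 (n = 2) in SPH and 363 ± 64.3 (n = 3) in METS. The arrays lay on 2 slides: slide 1 held DLD1, SA and SPH replicate 1, and slide 2 held SPH replicate 2 and METS. Levels below are log2 signals after division by each array's brightness, with a floor at -3.66, and changes are log2 fold changes ± SE from limma. Arrays at the floor show no spread, so the SE and p-values of miRNAs floored in a line can be too small. The miRNAs named as the largest changes had no overlap between the arrays of the sides compared. With so few arrays this is common. It held for 159 of the 239 tested miRNAs in SA versus DLD1, 178 in SPH versus DLD1 and 126 in METS versus DLD1. The numbers were 83 in SPH versus SA, 74 in METS versus SA and SPH, and 39 in SA and SPH versus DLD1 and METS. The number of arrays limits the precision of every value.

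The comparison of SA with DLD1 asked which miRNAs differed between cells labelled mesenchymal, from soft agar, and their epithelial parent. The largest increases were in miR-125b-5p, which rose from -2.38 ± 0.058 (SD, n = 2) to -0.91 ± 0.072 (SD, n = 3), a 2.77-fold increase (adjusted p = 2.1e-07), and in miR-100-5p, which rose 2.33-fold from -2.43 ± 0.044 to -1.21 ± 0.028 (adjusted p = 2.1e-07). The genes MIR100 and MIR125B1, which encode them, lie on either side of MIRLET7A2 in GRCh38, and miR-125b-5p has a further gene elsewhere. Among miRNAs well above background on every array of both lines, the next increases were in miR-148a-3p (0.85 ± 0.097, adjusted p = 0.00021), miR-375 (0.70 ± 0.076), miR-1260b (0.64 ± 0.11), let-7c-5p (0.51 ± 0.062) and miR-31-5p (0.49 ± 0.15, adjusted p = 0.049). The largest decreases were in miR-1246, which fell by 1.16 ± 0.11 (adjusted p = 9.4e-05), and miR-1290, which fell by 0.90 ± 0.13. miR-642b-3p, well above background on 1 of 3 SA arrays, fell by 0.73 ± 0.090, miR-193b-3p by 0.69 ± 0.076, miR-149-5p by 0.58 ± 0.13 and miR-4465 by 0.55 ± 0.10. let-7e-5p was well above background on both DLD1 arrays and on 1 of the 3 SA arrays, and its SA values lay at the floor (adjusted p = 2.7e-05).

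All 5 measured members of the intestinal epithelial list, miRNAs abundant in gut epithelium, rose in SA: miR-375, miR-194-5p by 0.45 ± 0.074, miR-192-5p by 0.44 ± 0.092, miR-203a-3p by 0.30 ± 0.085, and miR-215-5p, which was not well above background in DLD1 and was at least 1.35-fold higher in SA (adjusted p = 0.0092). The list as a set was higher (camera adjusted p = 5.9e-05; adjusted p = 0.18 with an estimated correlation), and 5 members were called when adjusted over the list alone. Of the 6 measured miRNAs on the mesenchymal-associated list, miR-125b-5p and miR-100-5p rose and 4 were not called, among them miR-21-5p at -0.073 ± 0.090 and miR-10b-5p at 0.18 ± 0.073. The list's test gave an adjusted p of 0.0046 (adjusted p = 0.42 with an estimated correlation). In the let-7 family, whose members restrain growth-promoting transcripts such as those of RAS genes, let-7a-5p, let-7b-5p, let-7c-5p and let-7f-5p rose, by 0.26 to 0.51, let-7e-5p fell and 4 of 9 were not called. The let-7 list had an adjusted p of 0.041 (adjusted p = 0.60 with an estimated correlation, adjusted p = 0.11 with brightness as a covariate). Among 12 measured members of the miR-17-92 cluster and its paralogues, a MYC-induced group, 4 fell, led by miR-92a-3p (-0.45 ± 0.066) and miR-17-5p (-0.42 ± 0.080), with 7 called when adjusted over the list alone. The test of this list gave an adjusted p of 0.0087 (adjusted p = 0.60 with an estimated correlation). miR-210-3p, the best known hypoxia-induced miRNA, fell by 0.35 (adjusted p = 0.0073). In total 41 of 239 miRNAs were called, 20 higher and 21 lower. Both lines lay on slide 1, and the count was 42 when slide was a block and 50 with slide 1 alone. The split depended on the scaling, with 28 higher and 16 lower after quantile normalization, 28 and 11 with the scanner's total signal per miRNA, 3 and 0 with the percentile over all probes, and 4 and 0 without scaling. The count was 27 without DLD1 replicate 1, 17 without DLD1 replicate 2 and 27 without SA replicate 2. It was 25 with the authors' table and 11 with no detection filter.

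In SPH, miR-125b-5p (1.48 ± 0.073, 2.79-fold, adjusted p = 3.7e-07) and miR-100-5p (1.40 ± 0.062, 2.63-fold, adjusted p = 2.8e-07) again had the largest increases over DLD1, followed by miR-148a-3p, which rose 2.13-fold (1.09 ± 0.11, adjusted p = 7.5e-05). miR-192-5p rose 1.75-fold from -2.16 ± 0.056 (SD, n = 2) to -1.36 ± 0.039 (SD, n = 2), and miR-194-5p rose 1.68-fold (adjusted p = 0.00015). miR-215-5p was at least 1.75-fold higher. With miR-375 at 0.28 ± 0.083 (adjusted p = 0.037, turning to -0.099 with normexp background correction), 4 of the 5 measured intestinal epithelial members rose, 4 of them also when adjusted over the list alone, and miR-203a-3p was at 0.017 ± 0.093. The list as a set was again higher (camera adjusted p = 0.00065, adjusted p = 0.26 with an estimated correlation), and within slide 1 its mean was 0.51 higher in SPH replicate 1 than in DLD1. The decreases were led by miR-1246 (fell by 1.25 ± 0.12, adjusted p = 7.5e-05), miR-193b-3p (fell by 0.88 ± 0.083), miR-642b-3p (fell by 0.77 ± 0.099), miR-1290 (fell by 0.74 ± 0.14), miR-6090 (fell by 0.68 ± 0.15) and miR-371b-5p (fell by 0.63 ± 0.20). The SPH values of miR-371b-5p lay at or just above the floor, and its call was lost under 20 alternatives. let-7e-5p was not well above background on either SPH array and was at least 2.13-fold lower than in DLD1 (adjusted p = 6.3e-05). Its values lay at the floor on all SA and SPH arrays, so this p-value can be too small.

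On the mesenchymal-associated list, miR-10b-5p joined miR-100-5p and miR-125b-5p with an increase of 0.41 ± 0.080, so 3 of 6 rose, 4 when adjusted over the list alone. miR-21-5p was at 0.27 ± 0.098 (list adjusted p = 0.00056, adjusted p = 0.26 with an estimated correlation). In the let-7 family 5 of 9 rose and let-7e-5p fell, 7 called when adjusted over the list alone (list adjusted p = 0.026, adjusted p = 0.46 with an estimated correlation, adjusted p = 0.099 with brightness as a covariate). From the miR-23-27-24 clusters, miR-27a-3p, miR-23a-3p, miR-27b-3p and miR-23b-3p rose by 0.28 to 0.37, 4 of 5 measured, with the same count when adjusted over the list alone (list adjusted p = 0.0036, adjusted p = 0.46 with an estimated correlation). The miR-183 cluster split, with miR-182-5p (0.45 ± 0.11, -0.023 with normexp background correction) and miR-96-5p higher and miR-183-5p lower (-0.42); its list was not called. miR-140-5p and miR-140-3p rose by 0.48 and 0.43, the first turning to -0.082 with normexp background correction. miR-34a-5p rose by 0.33 (adjusted p = 0.021). Among the miRNAs fixed in advance as having GC-rich, bright probes, 10 of 23 fell in SPH, 16 when adjusted over the list alone (list adjusted p = 0.00019, adjusted p = 0.46 with an estimated correlation and 0.14 with brightness as a covariate), on arrays that were brighter than those of DLD1. In SA 3 of the 23 fell, 0 when adjusted over the list alone (list adjusted p = 0.0087, adjusted p = 0.60 with an estimated correlation and 0.41 with brightness as a covariate). The 5 lists called here were also called with slide as a block. For SPH against DLD1 67 miRNAs were called, 29 higher and 38 lower. With slide as a block the count was 17, within slide 1 it was 22, and with brightness as a covariate 27. The split was 33 to 17 with the total signal per miRNA, 7 to 0 with the percentile over all probes and 9 to 0 without scaling. The count was 19 without DLD1 replicate 1, 27 without DLD1 replicate 2, 17 without SPH replicate 2 and 108 without METS replicate 2. It was 35 from the authors' table, 102 after normexp background correction and 11 with no detection filter. SPH had 1 array per slide, so here the slide block and leaving out SPH replicate 2 are the same fit and no separate checks.

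SA and SPH differed from DLD1 in largely parallel ways, and the direct comparison asked whether the mesenchymal lines differed from each other. Of the miRNAs called in each, 12 were higher in both and 15 lower in both, against 2.43 and 3.34 for independent lists of those sizes and a mean of 0.01 in simulated unchanged groups sharing the same DLD1 arrays. None was called in opposite directions. Across miRNAs, which are not independent replicates, the fold changes had a Pearson correlation of 0.89 against 0.53 in the simulations, and a covariance of 0.089 against 0.0064. With 1 DLD1 array set against SA and the other against SPH, the correlation was 0.83 and 0.77 in the 2 possible divisions and the covariance 0.086 and 0.081, a division made after the results were seen. Part of the excess of shared calls over independent lists may come from the shared arrays. No miRNA was called between SPH and SA (0 of 239 with limma, 38 at an unadjusted p under 0.05). The smallest adjusted p, 0.068, belonged to miR-375, which was 0.42 lower in SPH on the log2 scale, a miRNA chosen here after its value was seen. In simulated data for this comparison, 92.2% of changes of 0.5 on the log2 scale were recovered and 35.5% of changes of 0.25. The simulation changed 60 of 239 miRNAs and held no slide or brightness differences. It does not give the recovery where few miRNAs differ. By camera, the miR-200 family (adjusted p = 0.027), the mesenchymal-associated list (0.032), the miR-17-92 group (0.0043) and the miR-23-27-24 clusters (0.0079) were higher in SPH and the GC-rich-probe list lower (0.00091). None of these lists held a called miRNA, each had an adjusted p of 0.51 with an estimated correlation, and with slide as a block their adjusted p ranged from 0.15 to 0.40. When adjusted over the list alone, 3 of the mesenchymal-associated miRNAs were called and 0 of the other 4 lists. The intestinal epithelial list, not called as a set (list adjusted p = 0.38), had all 5 members called when adjusted over the list alone, 3 higher and 2 lower in SPH, and 5 further lists of 1 or 2 tested members had 1 each. With the mean of all probes 2 miRNAs were called, with brightness as a covariate 1, without SA replicate 3 1, and without METS replicate 2 2.

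**Figure D1:**
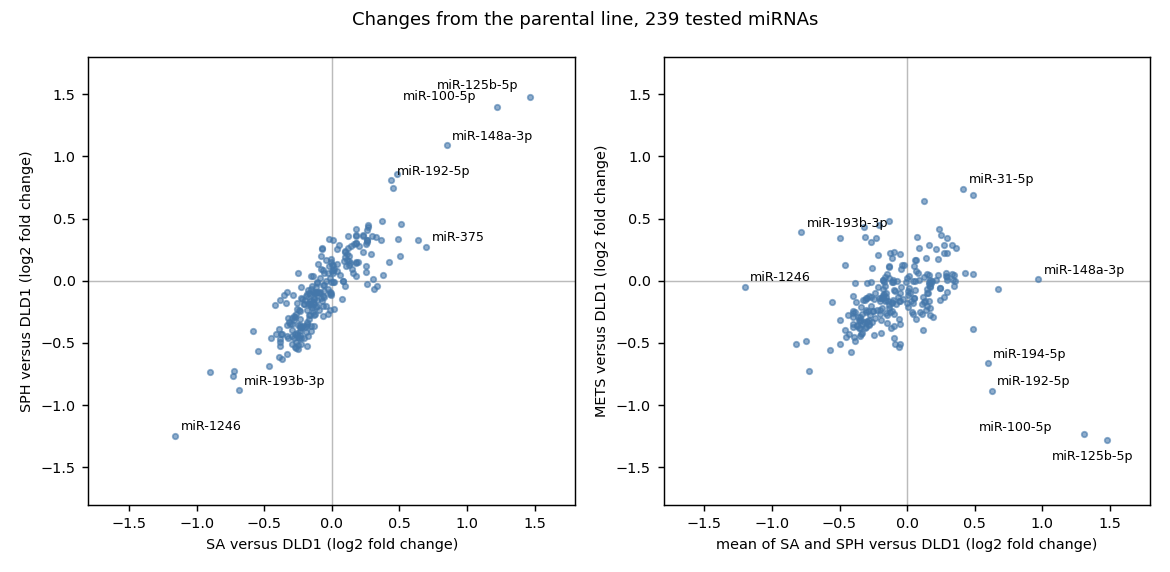
Log2 fold changes from DLD1 for the 239 tested miRNAs, 1 point per miRNA: SPH against SA on the left, METS against the mean of SA and SPH on the right. miR-125b-5p and miR-100-5p lie highest in both SA and SPH, at 1.22 to 1.48, and lowest in METS, where their values are at the floor.

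METS was compared with DLD1 to ask whether the epithelial cells recovered from a metastasis matched the epithelial parent. miR-100-5p and miR-125b-5p, raised in SA and SPH, were not well above background on any METS array and were at least 2.70-fold (adjusted p = 3.7e-07) and at least 2.78-fold (adjusted p = 6.3e-07) lower than in DLD1. miR-192-5p fell by 0.88 ± 0.092 to -3.05 ± 0.17 (SD, n = 3; adjusted p = 0.00018). miR-194-5p, well above background on 1 of 3 METS arrays, fell to the floor (-0.66 ± 0.074, adjusted p = 0.00025), and miR-375 was at least 1.50-fold lower (adjusted p = 0.0071). In the intestinal epithelial list 3 of 5 thus fell and miR-203a-3p rose by 0.29 ± 0.085; its set test gave an adjusted p of 0.30. miR-183-5p fell by 0.57 ± 0.081, and miR-320c, miR-320d and miR-320e each fell by 0.51 to 0.53. let-7e-5p lay at or just above the floor, with 1 of 3 METS arrays well above background (adjusted p = 2.8e-05), and the other 8 let-7 members were not called. miR-34a-5p fell by 0.27 (adjusted p = 0.027).

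The largest increases in METS were in miR-31-5p (0.74 ± 0.15, adjusted p = 0.0071), miR-1260b (0.69 ± 0.11), miR-222-3p (0.64 ± 0.073, adjusted p = 0.00025) and miR-221-3p (0.48 ± 0.095). The last pair, neighbours that repress the cell-cycle inhibitor CDKN1B, stand on the mesenchymal-associated list, of which 2 of 6 rose, 2 fell and 2 were not called (list adjusted p = 0.95). miR-193b-3p, lowered in SA and SPH, rose by 0.39 ± 0.076 from -2.20 ± 0.0066 (SD, n = 2) to -1.81 ± 0.063 (SD, n = 3), and miR-210-3p rose by 0.35. From the miR-17-92 group, miR-20b-5p (0.45 ± 0.10), miR-17-5p (0.35 ± 0.080) and miR-20a-5p (0.31 ± 0.084) rose, 3 of 12, the same number as when adjusted over the list alone (list adjusted p = 0.0043, adjusted p = 0.76 with an estimated correlation, 0.10 with brightness as a covariate and 0.35 with slide as a block). miR-29c-3p (0.42), miR-324-5p (0.37) and miR-4291 (0.36) completed the largest increases. In the miR-23-27-24 clusters miR-23a-3p rose by 0.29, -0.015 relative to the median shift under quantile normalization (list adjusted p = 0.046, adjusted p = 0.76 with an estimated correlation, 0.18 with brightness as a covariate and 0.96 with slide as a block), with 2 called when adjusted over the list alone. Of the GC-rich-probe list 8 of 23 fell, 13 when adjusted over the list alone (list adjusted p = 0.0061, adjusted p = 0.76 with an estimated correlation, 0.18 with brightness as a covariate and 0.91 with slide as a block).

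For METS against DLD1 60 miRNAs were called, 15 higher and 45 lower. DLD1 and METS shared no slide, and slide could be separated from line only through the 2 SPH arrays. With slide as a block 4 miRNAs were called, all lower: miR-100-5p, miR-125b-5p, miR-194-5p and let-7e-5p. The balance of higher and lower followed the scaling, with 23 and 22 after quantile normalization, 42 and 10 with the total signal per miRNA, 16 and 13 in the authors' table, and 0 and 2 both without scaling and with the percentile over all probes. The count was 17 without DLD1 replicate 1, 24 without DLD1 replicate 2 and 38 without METS replicate 3. It was 31 with only DLD1 and METS in the fit and 14 with no detection filter. Against a mean of 0.01 to 0.02 shared calls in simulated unchanged groups, SPH and METS shared 20 lower miRNAs (7.15 for independent lists) and 2 higher ones (1.82), and SA and METS shared 9 lower (3.95) and 4 higher (1.26). In opposite directions, 5 were higher in SA and lower in METS (3.77) and 4 the reverse (1.32), and 7 were higher in SPH and lower in METS (5.46) and 1 the reverse (2.38). The simulated value leaves out real effects and that of independent lists the shared DLD1 arrays, so the excess over either does not measure a shared effect, here or between SA and SPH. The fold changes of METS and of the mean of SA and SPH had a Pearson correlation of 0.12 across miRNAs, below the 0.65 of the simulations, with a covariance of 0.010 against 0.0066. Lower in all 3 derived lines were 8 miRNAs: let-7e-5p, miR-1268a, miR-1290, miR-183-5p, miR-4530, miR-6090, miR-642a-3p and miR-642b-3p. Of these, miR-1268a, miR-4530 and miR-6090 stand on the GC-rich-probe list. Only let-7e-5p, at or just above the floor in the derived lines, stayed called for METS versus DLD1 with slide as a block. Both SPH arrays lay at the floor for let-7e-5p, so the block could not remove a slide effect for it, and slide stays open.

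**Figure D2:**
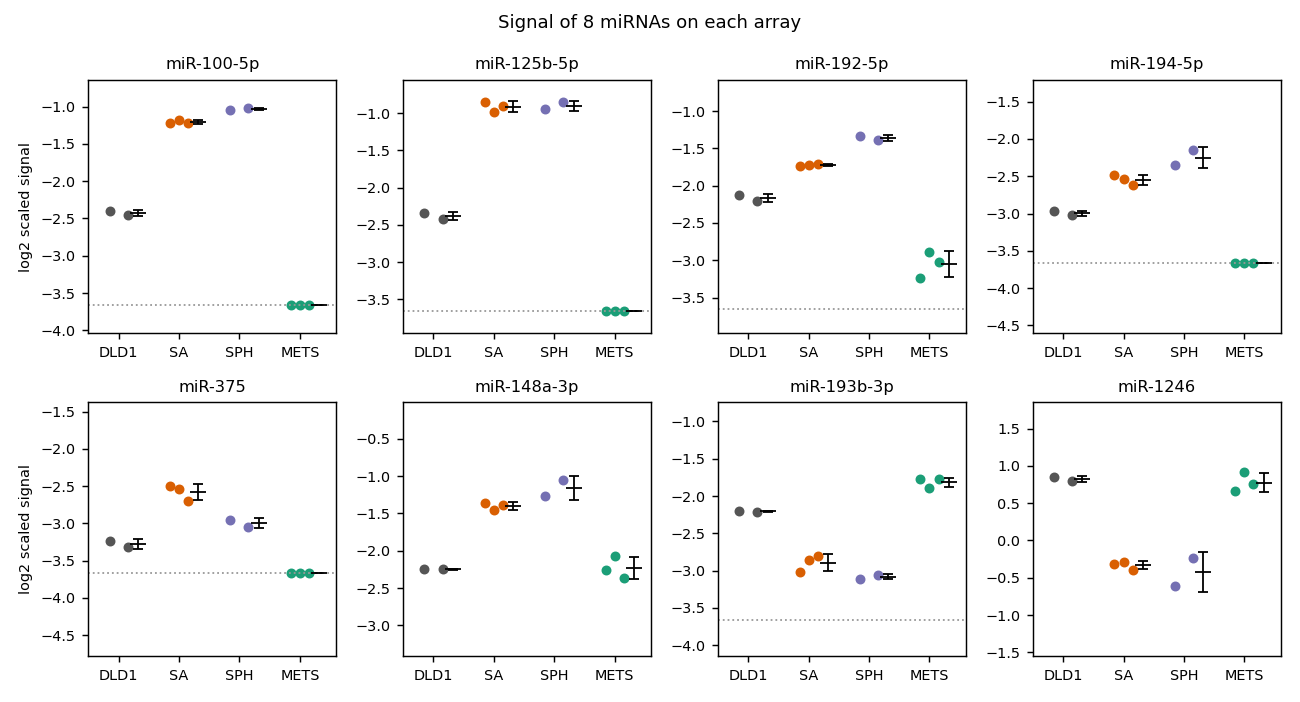
Log2 scaled signal (y axis) of 8 miRNAs on each of the 10 arrays by line (x axis), 1 point per array; bars show mean ± SD and dotted lines the floor at -3.66. All SA and SPH arrays lie above DLD1 and METS for the first 6 miRNAs and below them for miR-193b-3p and miR-1246.

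The METS line was next set against the mean of SA and SPH, the change from a mesenchymal to an epithelial label. miR-125b-5p and miR-100-5p were at least 7.73-fold and at least 6.67-fold lower in METS (adjusted p = 5.2e-11 and 4.6e-11). miR-192-5p fell by 1.51 ± 0.074 on the log2 scale (2.84-fold), miR-194-5p fell by 1.26 ± 0.060 with METS values at the floor, and miR-148a-3p fell by 0.96 ± 0.078. miR-375 and miR-215-5p, not well above background in METS, were at least 2.10-fold and at least 1.91-fold lower. The intestinal epithelial list therefore had 4 of 5 members lower, also when adjusted over the list alone, and miR-203a-3p at 0.13 ± 0.069 (list adjusted p = 0.0043; adjusted p = 0.58 with an estimated correlation, 0.058 with brightness as a covariate and 0.0013 with slide as a block). Within slide 2 the mean of this list differed by -0.91 between METS and SPH replicate 2. miR-193b-3p rose by 1.17 ± 0.061, miR-1246 by 1.15 ± 0.091, miR-149-5p by 0.84 ± 0.10 and miR-365a-3p by 0.75 ± 0.12. In the miR-17-92 group 8 of 12 rose, led by miR-17-5p (0.66 ± 0.064), miR-20b-5p (0.66 ± 0.082) and miR-20a-5p (0.58 ± 0.068), and miR-25-3p fell. There were 10 called when adjusted over the list alone (list adjusted p = 0.00021, adjusted p = 0.70 with an estimated correlation, 0.0082 with slide as a block). In the let-7 family 6 of 9 fell and miR-98-5p rose by 0.27 (list adjusted p = 0.11). miR-221-3p and miR-222-3p rose by 0.61 and 0.52, whereas the other 4 of the 6 measured mesenchymal-associated miRNAs fell (list adjusted p = 0.28). miR-210-3p rose by 0.58 (adjusted p = 3.7e-05). Overall counts were 80 called miRNAs, 28 higher and 52 lower, 36 with slide as a block. Within slide 2 the METS arrays differed from SPH replicate 2 in 8, with the single SPH array assumed to vary like the METS arrays. All 8 were among the 80 in the same direction, but these share their arrays with the 80 and are no separate evidence. The split was 46 to 34 with the total signal per miRNA and 24 to 26 in the authors' table. Without scaling and with the percentile over all probes 11 were called each, and 34 with no detection filter.

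The last comparison averaged the lines by label, SA and SPH against DLD1 and METS. The miR-200 family, whose members repress the transcription factors ZEB1 and ZEB2 and are used as markers of epithelial cells, was well above background on all 10 arrays for its 3p strands. miR-200c-3p measured 2.47 ± 0.025 (SD, n = 2) in DLD1, 2.47 ± 0.032 (n = 3) in SA, 2.60 ± 0.025 (n = 2) in SPH and 2.55 ± 0.051 (n = 3) in METS. miR-200b-3p measured 2.41 ± 0.066, 2.30 ± 0.043, 2.54 ± 0.0094 and 2.45 ± 0.091 in the same order. For miR-200a-3p the levels were -0.099 ± 0.10, -0.18 ± 0.15, 0.15 ± 0.22 and 0.16 ± 0.13, for miR-141-3p 1.12 ± 0.17, 1.23 ± 0.014, 1.24 ± 0.046 and 0.99 ± 0.22, and for miR-429 -0.16 ± 0.054, -0.24 ± 0.073, 0.041 ± 0.13 and 0.012 ± 0.14. None of these 5 was called in any of the 6 comparisons, nor by label under any scaling tried, where the differences of miR-200b-3p and miR-200c-3p changed sign with quantile normalization. Between the labels miR-200c-3p differed by 0.026 with a 95% confidence interval of -0.070 to 0.12, miR-200b-3p by -0.0033 (-0.12 to 0.11), miR-200a-3p by -0.042 (-0.24 to 0.15), miR-429 by -0.025 (-0.17 to 0.13) and miR-141-3p by 0.18 (-0.0066 to 0.37). The minor strands miR-200b-5p (-0.26 ± 0.054, adjusted p = 0.0048) and miR-200a-5p (-0.18, adjusted p = 0.047, 0.17 and not called with the total signal per miRNA) were lower in SA and SPH, so 2 of the 7 measured members fell (list adjusted p = 0.61). The values of miR-200a-5p lay at the floor on all SA and SPH arrays and on DLD1 replicate 1, where the sides overlapped. Its call or direction was lost under 22 alternatives, against 5 for miR-200b-5p.

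**Figure D3:**
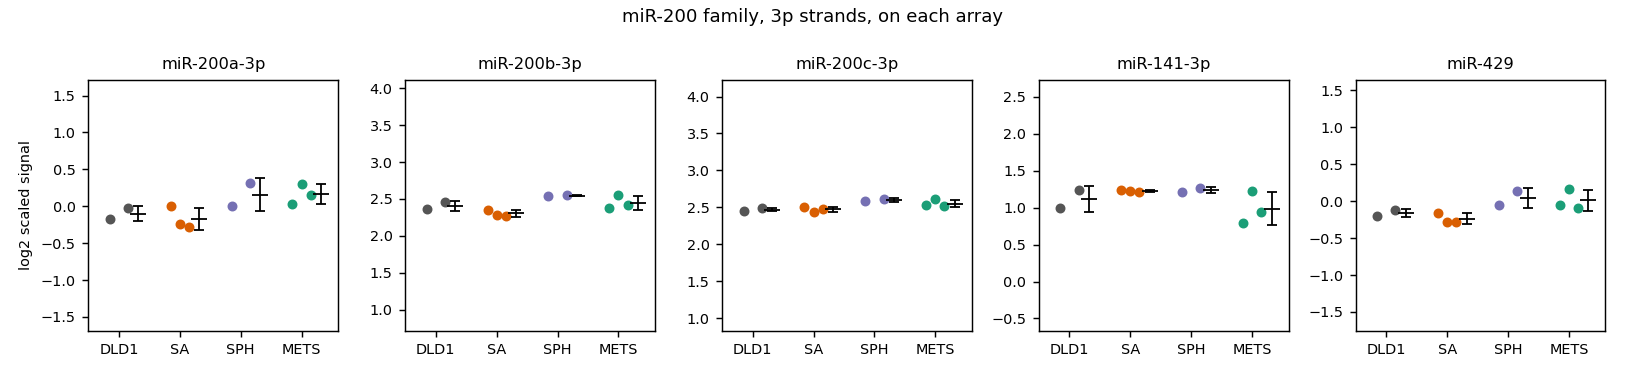
Log2 scaled signal (y axis, each panel spanning the same range of log2 units) of 5 miR-200 family members on each array by line (x axis), with mean ± SD. The SA and SPH arrays overlap the DLD1 and METS arrays in every panel, and miR-200c-3p stays between 2.47 and 2.60 in the means of all lines.

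By label, miR-125b-5p was at least 4.63-fold and miR-100-5p at least 4.06-fold higher in SA and SPH (adjusted p = 1.9e-10 for both, METS not well above background). miR-192-5p rose by 1.07 ± 0.065, miR-148a-3p by 0.96 ± 0.068 and miR-194-5p by 0.93 ± 0.052. miR-215-5p was at least 1.72-fold and miR-375 at least 1.71-fold higher. Thus 4 of 5 intestinal epithelial members were higher in the lines labelled mesenchymal, with the same count when adjusted over the list alone (list adjusted p = 0.00072, adjusted p = 0.31 with an estimated correlation, 0.0010 with slide as a block). Of the mesenchymal-associated list miR-125b-5p, miR-100-5p, miR-10b-5p (0.28 ± 0.052) and miR-21-5p (0.22) rose, and miR-221-3p (-0.37) and miR-222-3p (-0.20) fell, all 6 called when adjusted over the list alone (list adjusted p = 0.045, adjusted p = 0.60 with an estimated correlation and 0.14 with brightness as a covariate). The decreases of miR-221-3p and miR-222-3p by label came with their increase in METS: against DLD1 neither was called in SA (-0.17 and 0.15) or SPH (-0.10 and 0.098). let-7c-5p rose by 0.46 ± 0.044 and let-7b-5p by 0.37 ± 0.047, 6 of 9 let-7 members in all, with let-7e-5p lower (list adjusted p = 0.055). The largest decreases were in miR-1246 (fell by 1.18 ± 0.080), miR-193b-3p (fell by 0.98 ± 0.054), miR-149-5p (fell by 0.67 ± 0.090) and miR-92a-3p (fell by 0.52 ± 0.047), followed by miR-642b-3p, miR-17-5p, miR-4465, miR-431-3p, miR-17-3p and miR-378i. In the miR-17-92 group 7 of 12 fell, with 9 called when adjusted over the list alone (list adjusted p = 0.0046, adjusted p = 0.60 with an estimated correlation, 0.012 with slide as a block). miR-96-5p (0.32), miR-27b-3p (0.34), miR-34a-5p (0.30) and miR-140-5p (0.39, -0.00098 with normexp background correction) were higher, as was miR-182-5p (0.23, -0.0097 with normexp background correction). Of the GC-rich-probe list 2 of 23 fell (list adjusted p = 0.019, adjusted p = 0.60 with an estimated correlation and 0.72 with brightness as a covariate). In all 84 miRNAs were called, 50 higher and 34 lower. With slide as a block the count was also 84, 53 higher and 31 lower, but only 70 were the same miRNAs in the same direction. The split was 28 to 30 in the authors' table, 10 to 3 with the percentile over all probes and 15 to 3 without scaling. The count was 52 without DLD1 replicate 1, 53 without SPH replicate 2, 139 without METS replicate 2, 51 with 2 groups of 5 arrays and 25 with no detection filter.

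The remaining lists held few measured or called miRNAs. In the family of miR-15 and miR-16 miR-16-5p alone was called by label (0.20, list adjusted p = 0.19); in the miR-29 family miR-29b-3p alone (0.30, list adjusted p = 0.48); in the miR-30 family miR-30e-5p alone (0.29, list adjusted p = 0.34). Of the miR-181 family miR-181a-5p was called (0.20), and of miR-148a-3p and miR-148b-3p, of the same seed family, the first alone. In the cluster of miR-424 and miR-503 the 1 measured member, miR-424-5p, was not called (0.050). From the imprinted DLK1-DIO3 cluster, 87 miRNAs on the array, miR-431-3p fell (-0.38) and miR-494-3p was at -0.091. The 1 measured member of the embryonic clusters, miR-371b-5p, was at -0.34 (adjusted p = 0.059). The placental cluster, expressed from the paternal allele, had 0 of 48 miRNAs well above background on any array. Markers of other cell types were nearly all below background: 0 of 9 for fibroblasts and smooth muscle, 0 of 6 for skeletal and heart muscle, 0 of 4 for liver and neurons, and 1 of 2 for endothelium, miR-126-3p, on 2 arrays. Of 10 blood cell markers 1, miR-142-3p, was well above background, on all 5 SA and SPH arrays and on none of DLD1 or METS, at least 1.30-fold higher in SA than in DLD1 (adjusted p = 0.0051), with an adjusted p of 0.14 for SPH versus DLD1, and at least 1.46-fold lower in METS than in SA and SPH (adjusted p = 0.0050).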

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

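The test of slide for the 6 miRNAs below and the fits with brightness as a covariate were chosen after the results were seen. Against DLD1, 6 miRNAs moved one way in SA and SPH and the other way in METS, each past the threshold in all 3 comparisons. The increase of miR-375 in SPH was fragile. It lost its call or its direction under 19 alternatives, and turned negative with normexp background correction. The other calls of the 6 against DLD1 were lost under at most 6 alternatives each. The difference between METS and the mean of SA and SPH was itself tested. It was -2.54 for miR-100-5p, -2.75 for miR-125b-5p, -1.51 for miR-192-5p, -1.26 for miR-194-5p and -0.87 for miR-375, all higher in SA and SPH, and 1.17 for miR-193b-3p, lower there (adjusted p from 4.6e-11 to 3.4e-06). The METS values of miR-100-5p, miR-125b-5p, miR-194-5p and miR-375 lay at the floor, so these sizes are those of the floored fit. Their METS arrays show no spread, so their p-values can be too small.

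Slide does not account for the differences of SPH from DLD1 and from METS. SPH replicate 1 against DLD1 on slide 1 and SPH replicate 2 against METS on slide 2 kept a median of 0.974 of the pooled differences. The pooled differences contain the same SPH arrays, and neither comparison sets METS against DLD1. For METS against DLD1, which shared no slide, miR-100-5p, miR-125b-5p and miR-194-5p stayed past the threshold with slide as a block, and miR-192-5p (-0.83 ± 0.18, adjusted p = 0.067), miR-193b-3p (0.34 ± 0.14, adjusted p = 0.43) and miR-375 (-0.29 ± 0.14, adjusted p = 0.49) did not. Their differences without the block were -0.88 ± 0.092, 0.39 ± 0.076 and -0.39 ± 0.076, so the SE grew and the differences shrank. For these 3, slide stays open in METS against DLD1. With brightness as a covariate the differences between METS and SA and SPH kept a median ratio of 0.991, and each stayed past the threshold. A second probe measured miR-100-5p, miR-125b-5p and miR-192-5p and showed the same direction without overlap in 3 of 3 (a share of 1). Second probes counted only if above the floor on all SA and SPH arrays. Overlap is then impossible where METS lies at the floor, so the size is more telling. It was -2.00 for miR-100-5p and -1.28 for miR-192-5p, against -2.54 and -1.51 for the first probes. For miR-125b-5p it was only -0.25 against -2.75, so the second probe does not back that size. For miR-193b-3p, miR-194-5p and miR-375 there were 0 usable second probes, so 1 deviating probe per miRNA cannot be excluded for them, nor for the size of miR-125b-5p. DLD1 and METS share the epithelial label, but the 6 were chosen for differing between them, so that difference is no separate test of the labelled state. No biological explanation was tested: each line is 1 derivation, and labelled state, clonal origin, culture and other differences between the lines stay open.

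Other groupings bear on the counts. With 2 groups of 5 arrays, the mesenchymal and epithelial labels gave 51 called miRNAs. Of 100 splits, 1 gave as many, the real one. Arrays of a line resemble each other and most other splits break lines apart, so this count does not exclude chance. The highest other split gave 45. That split put DLD1 1, DLD1 2, SA 2, SA 3 and METS 1 on one side, mostly the dimmer arrays, which points to brightness as a second structure of these arrays. Splits of arrays do not test whether lines derived separately would differ as much without a change of state, which stays open. For METS against SA and SPH the real split gave 72 and 1 of 56 splits gave as many, the real one. This again does not exclude chance, since 1 of 56 is the smallest share possible, and differences between single derivations again stay open. The highest other split gave 11, the split that set SA 1, SPH 2 and METS 2, the 3 brightest arrays, apart.

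The GC-rich-probe list was lower than DLD1 by a mean of -0.42 ± 0.15 (SE) in SPH and -0.34 ± 0.14 in METS. Within lines the list's mean fell by 0.70 ± 0.13 per log2 unit of brightness, in all 23 members. These values were divided by the same brightness, so a probe of constant signal falls by construction. The slope and the ratios that follow are thus no separate evidence. With brightness in the model the SPH difference was -0.12 ± 0.083, a ratio of 0.276, and the METS difference -0.17 ± 0.065, a ratio of 0.494, which does not decide for METS. Before scaling the list differed from DLD1 by 0.015 ± 0.083 in SPH and -0.095 ± 0.076 in METS, so array brightness is a candidate explanation for SPH: these probes did not brighten while others did, and the scaling turns that into a decrease. Hybridisation or scanning is not the source of the brightness by the spike-in controls, whose slope on brightness was -0.166 ± 0.18; the amount or integrity of the small RNA was not tested and stays open.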

How the results depend on the processing

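Brightness as a covariate, the 2 brightest SPH and METS arrays left out and slide 1 alone were chosen after the data were seen. Of 172 called results for named miRNAs, 165 kept their direction under every alternative that gave them a value, relative to the median shift of a scaling. The larger median shifts, given below, were subtracted before directions were compared. The count therefore cannot tell whether a direction depends on the scaling. Without scaling, SPH versus DLD1 had 9 higher and 0 lower calls, against 29 and 38 in the main fit. Of the 165, 30 also kept their side of the threshold, among them miR-100-5p and miR-125b-5p in all 5 comparisons that called them. Both were above background on 7 arrays and not tested under the stricter detection filter, which gave values for 146 of the 172. Only the groups compared gave 129, slide 1 alone 68 and 2 groups of 5 arrays 43. Reversed were, with normexp, miR-140-5p (-0.082), miR-182-5p (-0.023) and miR-375 (-0.099) in SPH versus DLD1 and miR-140-5p (-0.00098) and miR-182-5p (-0.0097) in mesenchymal versus epithelial; with quantile normalization, miR-23a-3p in METS versus DLD1 (-0.015); and with the total signal per miRNA, miR-200a-5p in mesenchymal versus epithelial (0.17). The cause was not tested. Without scaling the median change against DLD1 shifted by 0.24 (SA), 0.44 (SPH) and 0.25 (METS), with the percentile over all probes by 0.23, 0.51 and 0.39, and for METS by 0.11 with quantile normalization and 0.17 with the total signal; mesenchymal against epithelial shifted by 0.22 without scaling and 0.18 with the percentile over all probes, SPH against SA by 0.20 and 0.28, and METS against SA and SPH by 0.10 with the total signal. miRNAs near background limit these results: the floor hides the size of their decreases. It also takes the spread out of floored arrays, so p-values of these miRNAs can be too small.

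Counts of called miRNAs that moved were as follows. The main counts were 41 (SA versus DLD1), 67 (SPH versus DLD1), 60 (METS versus DLD1), 0 (SPH versus SA), 80 (METS versus SA and SPH) and 84 (mesenchymal versus epithelial). The percentile over all probes gave 3, 7, 2, 0, 11 and 13, no scaling 4, 9, 2, 0, 11 and 18, and no detection filter 11, 11, 14, 0, 34 and 25 among 2549 tested. A change of at least 2-fold was reached by 3, 4, 2, 0, 6 and 4. The authors' table gave 25 for SA, 35 for SPH and 29 for METS versus DLD1 and 50 for METS versus SA and SPH; normexp gave 102 for SPH versus DLD1, only the groups compared 31 for METS versus DLD1, the mean of probes 2 for SPH versus SA, and 2 groups of 5 arrays 51 for mesenchymal versus epithelial. Slide as a block gave 17 for SPH versus DLD1, 4 for METS versus DLD1 and 36 for METS versus SA and SPH, and array row as a block 68 for SA and 116 for SPH versus DLD1. Brightness as a covariate gave 27 for SPH versus DLD1 and 1 for SPH versus SA, the 2 brightest arrays left out 67 for SA and 33 for SPH versus DLD1, and slide 1 alone 22 for SPH versus DLD1. Leaving out 1 array gave 17 to 56, 17 to 108, 17 to 70, 0 to 2, 57 to 90 and 52 to 139; a line left with 1 array was assumed to vary like the others. List tests, 24 of 66 called, gave 0 calls with an estimated correlation, 10 with brightness as a covariate, 20 after quantile normalization and 33 of 78 with the total signal.

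Replicate numbers did not pair the arrays: over 13 pairs with the same number the correlation of deviations ran from -0.67 to 0.51, and 9 lay at or below 0.1. The fit with the replicate number as a block called 30, 46, 44, 0, 73 and 65 miRNAs in the 6 comparisons.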

Other observations

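The count of neighbouring pairs that changed in the same direction was chosen as a test after the results were seen. In METS against DLD1, which shared no slide, the miR-320 family was lower: miR-320a was at -0.35 (adjusted p = 0.0044) and miR-320b at -0.46 (adjusted p = 0.00078), beside miR-320c, miR-320d and miR-320e, whereas in SA and SPH all 5 lay between -0.0096 and -0.13 and were not called. With slide as a block the 5 were at -0.26 to -0.39 and none was called (adjusted p from 0.12 to 0.42), as the differences shrank and the SE grew from at most 0.074 to at least 0.10. SPH 2, on the slide of METS, was also lower than SPH 1 for all 5, by 0.085 to 0.20, so part of the decrease cannot be told apart from slide. Within slide 2, METS differed from SPH 2, a single array, by -0.22 to -0.35 for all 5. miR-320a and miR-320b were chosen after their values were seen, and the family's probes can cross-hybridise. miR-365a-3p, whose gene MIR365A lies beside MIR193B in GRCh38, was lower in SA and SPH than in DLD1 and METS (-0.54, adjusted p = 0.0043), as was miR-193b-3p (-0.98). Against DLD1 alone miR-365a-3p was not called, at -0.30 in SA (adjusted p = 0.18, with overlapping arrays), -0.35 in SPH (adjusted p = 0.12) and 0.43 in METS (adjusted p = 0.064).

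The pair of miR-365a-3p and miR-193b-3p led to the hypothesis that shared transcription of neighbouring genes makes neighbouring miRNAs move together, which may also hold for miR-192-5p with miR-194-5p. Among tested miRNAs, 57 pairs of different seed families had genes within 50 kb. Their mesenchymal versus epithelial changes differed by a median of 0.20, against 0.22 in 10000 permutations (permutation p = 0.32). With the 6 miRNAs of opposite direction left out, 50 pairs remained, with a median difference of 0.18 against 0.22 (permutation p = 0.154). By direction alone, neighbours were more alike: 45 of the 57 pairs changed in the same direction, against a median of 29 in permutations (permutation p = 0.00070), and 38 of the 50 against 25 (permutation p = 0.0032). These pairs repeat the same seed families, whose probes can cross-hybridise. Over pairs of families, by family means, 21 of 28 shared their direction against 15 (permutation p = 0.023), and 15 of 22 against 11 with the 6 miRNAs left out (permutation p = 0.128). Shared transcription is thus neither shown nor excluded: let-7a-5p, whose gene MIRLET7A2 lies near MIR100 in GRCh38, changed by 0.33 beside 1.92 for miR-100-5p, but let-7a-5p also has other genes.

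Of the values in the authors' deposited table, 8 came from 1 bright spot each among 5 spots, each carrying an outlier flag in the scanner file. The authors' deposited table gives 61288 for miR-92a-2-5p in METS 3, where the median spot was 39 and the highest other array was 47.7, and 46778 for miR-922 in SA 3, where the median spot was 37.5. Neither miRNA was tested here.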
